A study of Mus musculus with 6 samples.

How the data were processed

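Total RNA from whole lateral ventricle choroid plexus of male CD1 mice, an outbred stock, was measured on 6 Affymetrix Mouse Genome arrays, 3 from mice aged 18 months and 3 from mice aged 2 months. Each array held both lateral ventricle plexuses of 1 mouse, so that an array stands for an animal. Per the labels' protocols, RNA was extracted with the miRNeasy kit, amplified to cDNA with a Nugen Pico kit and labelled with biotin. Amplification of small inputs can distort the levels of dim and partly degraded transcripts, and the array reports relative levels of one transcript between samples, not the abundance of one transcript against another.

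The authors deposited 1 table of normalized intensities for the 45101 probe sets. Per the submitters' processing notes the values were made with RMA, which corrects background, normalizes between arrays and summarises the probes of each probe set. No version was given in the sources used here. RMA values are usually on a log2 scale, but the deposited intensities ran from 2.47 to 26820.7 and were therefore on a linear scale. Their log2 was taken before any step described here. The median log2 value of the arrays lay between 5.56 and 5.65. No 2 arrays held identical values, and the table had no columns from other samples.

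Probe sets were named through the platform annotation. Of 45037 probe sets that are not Affymetrix controls, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none. Probe sets with several symbols were not used for genes. Symbols were checked by gene identifier against a RefSeq gene table (assembly GRCm38.p6), and 0 changed. No genome build was named with the array values, and no coordinates are given. For each of 18193 genes the probe set with the highest mean log2 value over the 6 arrays stood for the gene. A gene was tested if that mean reached the 40th percentile of all non-control probe sets, a log2 value of 4.92. This left 12681 genes. As a gauge of background, 27 control probe sets for bacterial transcripts had a median log2 mean of 3.03 and a highest mean of 4.51.

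Ages were compared with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, 18 months minus 2 months, two-sided, without covariates), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Errors of differences are standard errors (SE) from that fit, and intervals are 95% confidence intervals. The moderated test had 6.61 degrees of freedom. Spreads of group means are standard deviations (SD) over 3 mice. The number of arrays limits the precision of every value.

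A total of 39 gene lists (tissue, cell type, pathway and secreted-factor lists, 1026 distinct symbols) were written before the data were examined, together with the tests, the alternatives and the rule for naming genes. For 96 of the symbols no probe set was named for that gene alone here. Of the listed genes, 731 were tested. Lists with at least 5 tested genes were compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the 39 lists. Camera with an estimated correlation and fry were run beside it. The rule named the genes past the threshold with the largest changes, or, where fewer than 5 passed in a direction, the 10 with the smallest p in that direction, whose values are then given as measured. Symbols that are only clone or model numbers were left out of that part. It also named up to 4 members of each list with the smallest p and 17 genes fixed by name. For genes on the 6 lists of secreted factors, p-values were also adjusted over those genes alone. The same was done within each other list, outside the written plan and without correction across lists. For control probe sets, differences between the 3' and 5' ends were compared by an exact permutation test, for which 3 mice against 3 allow no p below 0.1.

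Both tests were first tested on simulated data with the real means of the 12681 genes and their spreads as moderated by limma. There were 20 simulations with 200 changed genes each. The limma test called 18.3% of genes changed 2-fold, 85.5% of those changed 4-fold and 96.6% of those changed 8-fold, with 5.33% false calls among all calls. Moderated spreads differ less between genes than measured ones, and the planted changes ease the adjusted threshold. These shares can therefore overstate how many real changes would be called here. Camera called a list of 20 genes shifted by 0.5 on the log2 scale in 20 of 20 simulations in which genes varied independently. In the real data the estimated correlation was near 0 for some lists and higher for others. It was 0.153 for MHC class II genes and 0.734 for oligodendrocyte markers. The simulations therefore do not gauge how often camera calls real lists wrongly.

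The alternatives were no filter, a 60th percentile filter, the mean of all probe sets of a gene, quantile normalization, centring of each array on its median, leaving out each mouse in turn, the replicate number as a block, array weights, a prior variance with trend and robust estimation, an ordinary 2-sample test with equal variance, an adjusted p under 0.10, a minimum change of 1.5-fold, and list tests without genes shared between lists. After the data were seen, a covariate for the level of neuron markers and a fit without the arrays at both ends of principal component 1 were added.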

Results

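The choroid plexus, the epithelial tissue that makes cerebrospinal fluid, was profiled in male CD1 mice at 2 ages. The question was how its transcripts differ between young and aged animals, in particular those for factors released into the fluid that bathes the adult neural stem cell niche. The data were 6 arrays from 6 mice, 3 aged 18 months and 3 aged 2 months. Ttr, which encodes the thyroxine carrier transthyretin made by the plexus epithelium, had a log2 intensity of 14.30 ± 0.05 (SD, n = 3) at 18 months and 14.47 ± 0.01 (SD, n = 3) at 2 months. Kl, which encodes the anti-ageing hormone co-receptor Klotho, had 12.50 ± 0.06 and 12.44 ± 0.12 (SD, n = 3 each).

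The samples also held brain tissue in amounts that varied from mouse to mouse. Snap25, a synaptic gene, had log2 intensities of 10.43, 11.63 and 12.29 in the 3 mice at 18 months and 11.10, 10.23 and 12.30 in those at 2 months. Mbp, a myelin gene, had 10.21, 11.14 and 11.79 at 18 months and 11.23, 10.01 and 11.85 at 2 months. Over all 12681 genes tested, arrays of 1 age correlated at 0.944 (18 months) and 0.942 (2 months) on average, against 0.938 between ages. Of the variance, 23.9% lay between ages, where 20% is expected by chance. Principal component 1 held 28.5% of the variance and placed 18-month replicate 3 and 2-month replicate 2 at its ends. The log2 difference between the 3' and 5' control probe sets was 1.41 ± 0.16 at 18 months and 1.57 ± 0.12 at 2 months for Gapdh (SD, n = 3 each; exact permutation p = 0.3). For beta-actin it was -0.19 ± 0.08 and -0.21 ± 0.23 (exact permutation p = 1, two-sided, smallest possible p 0.1).

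The genes with the smallest p among those higher at 18 months were led by H2-Aa, the alpha chain of an MHC class II molecule, with a log2 intensity of 9.52 ± 0.36 at 18 months against 6.34 ± 0.24 at 2 months (SD, n = 3 each). This is a log2 difference of 3.18 (SE 0.24, adjusted p = 0.0540), or 9.07-fold. Spns2, a transporter that exports sphingosine-1-phosphate, was measured at 4.13-fold (log2 difference 2.05, SE 0.17). Samd9l, an interferon-inducible gene, was at 4.89-fold (2.29, SE 0.22) and Flvcr2, a membrane transporter, at 3.24-fold (1.70, SE 0.17). Gh, the growth hormone of the pituitary, had the largest difference of the named genes, 4.98 (SE 0.45, adjusted p = 0.0540), from 4.91 ± 0.63 to 9.89 ± 0.71 (SD, n = 3 each). All 4 of its probe sets were higher, by 3.64 or more over the larger of the 2-month mean and the highest bacterial control. The others were the growth factor receptor gene Pdgfra (1.95, SE 0.22), Serpina1c of the alpha-1-antitrypsin family (2.82, SE 0.32). Next came Wfikkn2, which encodes a secreted binder of growth and differentiation factors (2.38, SE 0.30), the homeobox gene Dlx4 (1.34, SE 0.18; 1.23 over background, where its 2-month mean lay) and the complement protease gene C1ra (2.00, SE 0.27). The 3 probe sets for Pdgfra disagreed, with differences from 0.04 to 1.95, as did the 3 above the filter for H2-Aa, from 0.73 to 3.18. Serpina1c has close paralogs that its probe set may also read.

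Among genes lower at 18 months the smallest p belonged to Akr1b10, an aldo-keto reductase gene, at 5.54 ± 0.07 against 7.35 ± 0.17 (SD, n = 3 each), a log2 difference of -1.81 (SE 0.17, adjusted p = 0.0540) or 3.51-fold. Its 2 other probe sets lay below the filter and gave 1.15 and -0.66, and the mean of all 3 gave -0.44 (adjusted p = 0.726). The bone morphogenetic protein gene Bmp5 had a log2 intensity of 5.11 ± 0.65 at 18 months against 7.63 ± 0.31 at 2 months (SD, n = 3 each), a difference of -2.51 (SE 0.36, adjusted p = 0.185) or 5.70-fold. Rad51b, a recombination gene, differed by -2.10 (SE 0.29) and the lysophosphatidic acid receptor gene Lpar4 by -1.98 (SE 0.27). Their means at 18 months, 4.14 and 4.32, lay under the highest bacterial control (4.51), so that their 2-month means exceed background by only 1.74 and 1.79. The scavenger receptor gene Colec12 differed by -1.69 (SE 0.27) and the matrix gene Postn by -1.30 (SE 0.20). Cfap161, which encodes a protein of motile cilia, differed by -1.96 (SE 0.32) and Mdh1b by -1.21 (SE 0.19). The Hedgehog co-receptor gene Cdon differed by -1.13 (SE 0.18) and the homeodomain gene Hopx by -1.23 (SE 0.20). For each of these 20 genes, all 3 mice of one age lay beyond all 3 of the other, which choosing genes by smallest p largely ensures.

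**Figure D1:**
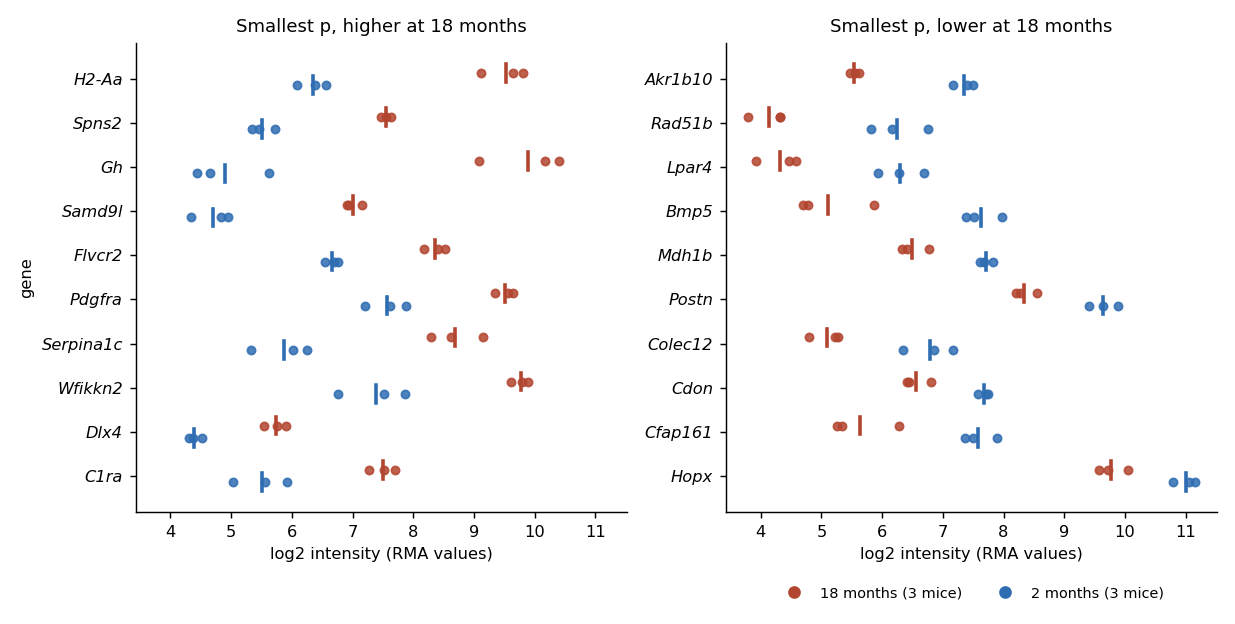
Log2 intensity (x axis) of the 10 genes with the smallest p in each direction (y axis), as 1 point per mouse, red for 18 months and blue for 2 months, with a vertical bar at the mean of 3 mice. The points of the 2 ages do not overlap for any of these genes, which choosing them by smallest p largely ensures. Gh differs by 4.98 and Akr1b10 by -1.81.

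None of these genes passed the threshold. By limma, 0 genes were higher and 0 were lower at an adjusted p under 0.05, the lowest adjusted p being 0.0540. At an unadjusted p under 0.05 there were 510 genes higher and 384 lower, 894 in all against 634 expected with no effect. An ordinary 2-sample test with Benjamini-Hochberg adjustment also gave 0 and 0. The ranges of the 2 ages were separate for 895 genes that were higher and 793 that were lower, 13.3% of those tested, where 10% is expected by chance. At an adjusted p under 0.10, 5 genes were higher (H2-Aa, Spns2, Gh, Samd9l and Flvcr2) and 1 was lower (Akr1b10). With a 60th percentile filter or with array weights, Gh, H2-Aa, Spns2 and Akr1b10 passed 0.05. With the mean of all probe sets Gh, Spns2, Samd9l, Flvcr2 and H2-Ab1 did.

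The lists with the smallest p were those of MHC class II genes and of macrophage markers. Genes of MHC class II and of the interferon-gamma response were higher relative to other genes (13 tested, 9 above 0, median log2 difference 1.04, camera adjusted p = 3.66e-06; adjusted p = 0.224 with an estimated correlation). Besides H2-Aa these were H2-Ab1, the partner beta chain, at 6.11-fold (2.61, SE 0.41), and Cd74, the invariant chain that escorts class II molecules, at 5.33-fold (2.41, SE 0.41). The interferon-induced GTPase gene Irgm2 was among them too (1.94, SE 0.51). Adjusted over the list alone, 6 genes rose and 0 fell. The median depended on the filter, at 0.53 with none and 1.45 with the 60th percentile. Markers of macrophages and microglia were also higher relative to other genes (21 tested, 17 above 0, median 0.40, camera adjusted p = 0.000979, and 0.224 with an estimated correlation). The 2 lists were not tested against each other. The largest were the membrane protein gene Ms4a7 (2.04, SE 0.35) and the lysozyme genes Lyz1 (1.94, SE 0.37) and Lyz2 (1.36, SE 0.31), paralogs whose probes may read one another. Cybb of the phagocyte oxidase gave 1.19 (SE 0.38). The median of the list was 0.20 with the mean of all probe sets and 0.23 without both arrays at the ends of component 1. Other markers ranged from Aif1 at 1.34 (SE 0.44) and Csf1r at 0.59 (SE 0.41) to Cd68 at 0.20 (SE 0.19) and Tyrobp at -0.46 (SE 0.37), or -0.08 without 2-month replicate 2. These 4 were named after their values were seen. Csf1r had 10.94, 10.09 and 10.60 at 18 months and 9.71, 9.36 and 10.79 at 2 months, so that its difference depends on single mice. MHC class I and immunoproteasome genes (13 tested, 9 above 0, median 0.30, camera adjusted p = 0.0176; adjusted p = 0.224 with an estimated correlation) were also higher relative to other genes. Among them were the proteasome subunit gene Psmb8 (1.25, SE 0.24), H2-D1 (1.30, SE 0.27), H2-K1 (0.83, SE 0.25) and B2m (0.30, SE 0.15). Variants in H2-D1 and H2-K1, which could change probe binding in outbred mice, were not tested. Without 18-month replicate 2 that list's median was 0.10 and its adjusted p 0.151.

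Chemokine and cytokine genes were higher as a list (17 tested, 13 above 0, median 0.43, camera adjusted p = 0.0196; adjusted p = 0.224 with an estimated correlation). Its members included Il18 (0.90, SE 0.19), Cxcl14 (1.65, SE 0.61), the B cell attractant Cxcl13 (1.17, SE 0.48) and Tnfsf10 (0.51, SE 0.22). Cxcl14 gave 0.94 without 2-month replicate 2 and Cxcl13 0.73 without 2-month replicate 3. The call was lost without 18-month replicate 3 (adjusted p = 0.134) or 2-month replicate 2 (0.0785). It was also lost with no filter (median 0.10, 0.0586) or a 60th percentile filter (0.25, 0.149), and the median was 0.27 without 18-month replicate 2. Type I interferon-stimulated genes did not pass (22 tested, median 0.13, camera adjusted p = 0.308). Of these, Irf9 differed by 0.79 (SE 0.23), Ifit3 by 0.76 (SE 0.31) and Ifit1 by 0.91 (SE 0.44). Over the alternatives Ifit3 ranged from 0.41 to 1.02 and Ifit1 from 0.53 to 1.54. Lgals3bp differed by 0.39 (SE 0.19) and the interferon regulator gene Irf7 by -0.46 (SE 0.33). The complement list did not pass either (15 tested, median 0.00, adjusted p = 0.713). C1ra and C1s1 (1.28, SE 0.34), which encode the partner proteases of the first complement component, lay among its highest. C1qb gave 0.68 (SE 0.27) and Cd55 -0.47 (SE 0.20). Of lymphocyte markers only 5 genes were bright enough to test (median -0.13, adjusted p = 0.865). The T cell marker Cd8a differed by 1.60 (SE 0.79), with 6.90, 8.55 and 5.11 at 18 months against 5.16, 5.26 and 5.33 at 2 months. Mzb1 gave -0.65 (SE 0.27), Jchain 0.47 (SE 0.31) and Ighm -0.58 (SE 0.42).

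Markers of multiciliated and ependymal cells, which line the ventricle next to the plexus, were lower at 18 months (24 tested, 20 below 0, median -0.30, camera adjusted p = 0.00377; adjusted p = 0.239 with an estimated correlation). The cilium genes 1700012B09Rik (-1.41, SE 0.31) and Mlf1 (-0.82, SE 0.19) fell when adjusted over the list alone, narrowly (limma, adjusted p = 0.0497 for each). Adjusted over all genes, their limma p was 0.470 and 0.494. Fam183b differed by -2.81 (SE 0.77) and Hdc, the histamine-forming enzyme gene, by 0.31 (SE 0.15). Without 2-month replicate 3 the median was -0.14 and the adjusted p 0.0872. Fewer such cells in a sample and a lower level per cell were not separated here. Genes of the unfolded protein response and chaperones of the endoplasmic reticulum were also lower (24 tested, 17 below 0, median -0.18, camera adjusted p = 0.0149; adjusted p = 0.224 with an estimated correlation). Smallest in p were the co-chaperone gene Dnajb11 (-0.49, SE 0.18), the stress transcription factor gene Atf4 (-0.50, SE 0.19), Sdf2l1 (-0.49, SE 0.19) and Manf (-0.38, SE 0.17). This call was lost without 18-month replicate 3 (0.0697) or 2-month replicate 1 (0.0525).

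Genes of the circadian clock and its output were higher at 18 months (18 tested, 14 above 0, median 0.53, camera adjusted p = 0.00187; adjusted p = 0.224 with an estimated correlation). The period gene Per3 (1.16, SE 0.23) and the repressor gene Bhlhe40 (0.98, SE 0.22) rose when adjusted over the list alone. Adjusted over all genes, their limma p was 0.390 and 0.471. Over the alternatives Per3 ranged from 0.27 to 1.29 and Bhlhe40 from 0.83 to 1.12. The output transcription factor genes Hlf (0.68, SE 0.22) and Dbp (0.84, SE 0.29) lay in separate ranges. Immediate-early genes, which respond within minutes to stimulation or handling, were higher as well (26 tested, 21 above 0, median 0.36, camera adjusted p = 0.00187; adjusted p = 0.224 with an estimated correlation). Of these, Fos differed by 1.79 (SE 0.47), or 3.46-fold, Fosl2 by 0.93 (SE 0.21), Jun by 0.56 (SE 0.19) and Ccn1 by 0.98 (SE 0.41). Without both arrays at the ends of component 1 the median of the list was 0.16 and its adjusted p 0.0571. Glucocorticoid-induced genes gave a median of 0.21 (17 tested, 11 above 0, camera adjusted p = 0.0242; adjusted p = 0.224 with an estimated correlation). The list was led by Tsc22d3 (1.25, SE 0.30) and Fkbp5 (0.59, SE 0.17), with Plin4 at 0.54 (SE 0.26) and Mt1 at 0.28 (SE 0.18). Without 18-month replicate 2 or 3 or 2-month replicate 2 its adjusted p was 0.0941, 0.0697 or 0.0649, and with the neuron covariate 0.0635.

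**Figure D2:**
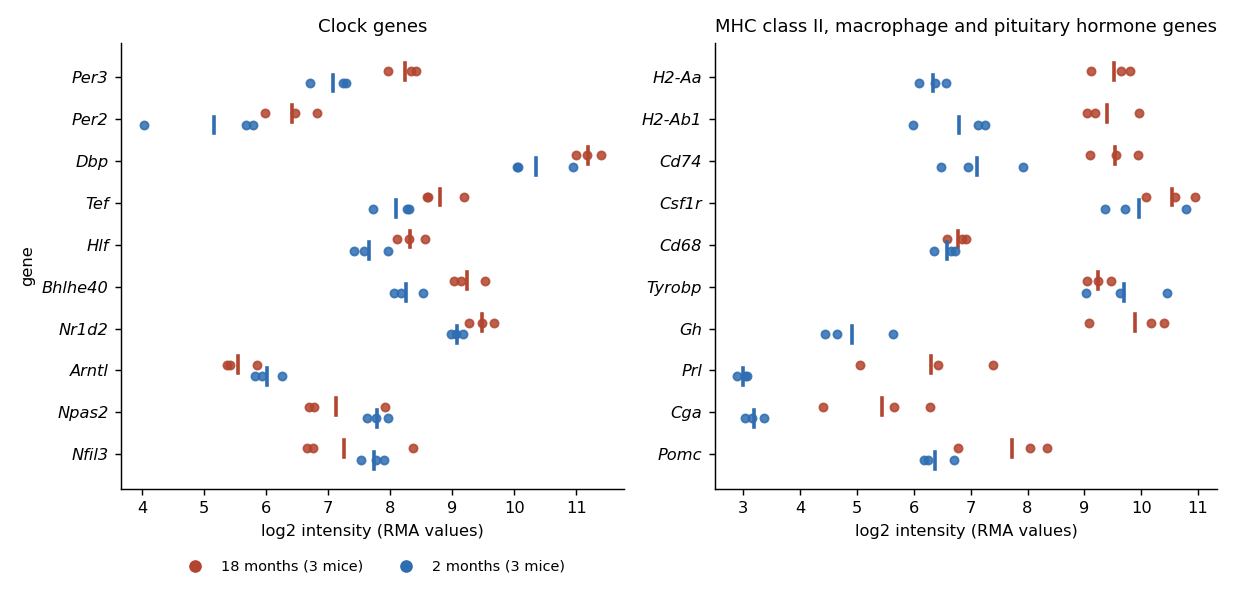
Log2 intensity (x axis) of clock genes (left) and of MHC class II, macrophage and pituitary hormone genes (right), 1 point per mouse, red for 18 months and blue for 2 months, with a bar at the mean of 3 mice. H2-Aa, H2-Ab1, Cd74 and Gh lie apart between ages, while Csf1r and Cd68 overlap. Per3 lies higher and Arntl differs by -0.46 at 18 months. The genes shown were picked by hand. Not shown are the clock genes Per1, Nr1d1, Ciart, Bhlhe41 and Clock and the hormone genes Tshb, Lhb and Fshb, which overlap between ages. The macrophage marker Aif1, which lies higher at 18 months, is not shown either.

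Genes of cholesterol synthesis and uptake were higher relative to other genes (20 tested, 14 above 0, median 0.20, camera adjusted p = 0.0242; adjusted p = 0.224 with an estimated correlation). The enzyme gene Nsdhl (0.94, SE 0.23), Insig1 (0.96, SE 0.24), Fdft1 (0.53, SE 0.19) and Cyp51 (0.65, SE 0.25) had the smallest p. The call was lost without 18-month replicate 1 (0.0585) or 3 (0.0669) and without 2-month replicate 1 (0.0625) or 3 (0.0922). Glycolysis genes gave a median of 0.15 (17 tested, 15 above 0, camera adjusted p = 0.0258; adjusted p = 0.244 with an estimated correlation). Hk2 (0.68, SE 0.23) and Ldha (0.38, SE 0.16) came first, then Aldoc (0.54, SE 0.30) and Pfkfb3 (0.57, SE 0.38). That call was lost without 18-month replicate 2 (0.170) or 2-month replicate 1 (0.0966) or 3 (0.0764), and without genes shared between lists (0.0568). Oligodendrocyte markers, which belong to brain tissue, also passed (14 tested, 13 above 0, median 0.37, camera adjusted p = 0.0169; adjusted p = 0.880 with an estimated correlation). Smallest in p here were Mog (1.75, SE 0.33), Ermn (2.26, SE 0.88), Apod (0.60, SE 0.25) and Aspa (0.79, SE 0.48). Over the alternatives Ermn ranged from 1.09 to 3.20 and Aspa from 0.29 to 1.32. The list itself depended on single arrays. Without 18-month replicate 3, an array with much brain signal, the median was -0.07 (adjusted p = 0.641), and without 2-month replicate 2 it was 0.02 (0.753).

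**Figure D3:**
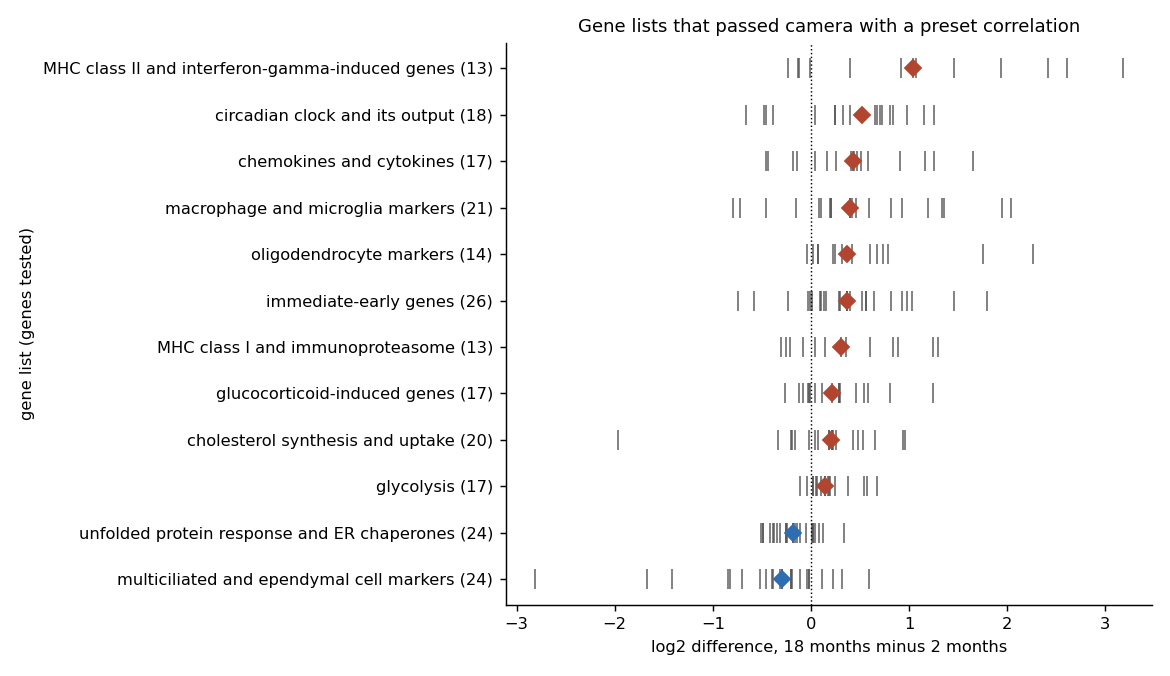
Log2 difference between ages (x axis, 18 months minus 2 months) of every tested gene (grey ticks) and the median (diamond, red if higher and blue if lower) of the gene lists that passed camera with a preset correlation (y axis, genes tested in brackets). The median runs from 1.04 for MHC class II genes to -0.30 for multiciliated and ependymal cell markers, and members of each list spread widely around it.

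In all, 10 lists passed in the upward and 2 in the downward direction by camera. With an estimated correlation 0 of the 39 lists passed an adjusted p of 0.05 and 8 had an unadjusted p under 0.05. Fry called 1 list in one direction, the matrix proteases, and 15 lists when members could go either way. These 15 included stroma (adjusted p = 0.00169), complement (0.00301) and BMP ligands (0.00615), none of which passed camera. Without 18-month replicate 3 the lists higher numbered 6, and without 2-month replicate 1 or 3 the lists lower numbered 1.

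For secreted factors, the question of the study, 107 genes on the 6 lists were tested. These lists also hold some genes for proteins that are not secreted, such as the receptor genes Igf1r and Insr and the intracellular Irs1 and Igf2bp3. By limma 0 of the 107 genes passed an adjusted p of 0.05 over all genes. At an unadjusted p under 0.05, 9 were higher and 1 lower, and 0 passed by the ordinary 2-sample test. Adjusted over the list alone, Wfikkn2 rose 5.22-fold, from 7.38 ± 0.56 to 9.77 ± 0.14 (SD, n = 3 each; adjusted p = 0.0134). Bmp5 fell 5.70-fold (adjusted p = 0.0145). The brightest of the Bmp5 probe sets gave -2.51, the dimmer one above the filter -0.80 and one below the filter -0.42. With the mean of all its probe sets Bmp5 differed by -1.24 and lost the call (limma, adjusted p = 0.0614 over the list alone). Il18 came next (adjusted p = 0.0928). The 2 calls were lost without 18-month replicate 2 or 3 or 2-month replicate 2, each leaving 0, and 1 was lost without 2-month replicate 1 or 3.

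No insulin-like growth factor gene passed the threshold. Igf1, a growth factor that acts on neural stem cells, had a log2 intensity of 7.75 ± 0.66 at 18 months against 8.60 ± 0.31 at 2 months (SD, n = 3 each), a difference of -0.85 (95% interval -1.70 to 0.00, adjusted p = 0.709). Its 4 probe sets lay between -2.33 and -0.55, and without 18-month replicate 3 the difference was -0.55. Igf2 differed by 0.06 (95% interval -0.30 to 0.41) and the receptor gene Igf1r by 0.26 (SE 0.18). Igfbp3 differed by -0.37 (SE 0.24) and Ins2 by -0.30 (SE 0.22), and the interval for Igfbp2 was -0.37 to 0.37. The list as a whole had a median of 0.03 (16 tested, camera adjusted p = 0.888). In the list of BMP and TGF-beta ligands (20 tested, median -0.03, adjusted p = 0.913) Bmp4 differed by 0.71 (SE 0.22), Chrd by 0.47 (SE 0.27) and Bmp7 by -0.20 (SE 0.20). Nog lay below the filter. The list with genes of the FGF, EGF and VEGF families did not pass (22 tested, 16 below 0, median -0.12, adjusted p = 0.274). Fgf2 differed by -0.75 (SE 0.76), Vegfb by 0.51 (SE 0.23), Fgf13 by -0.81 (SE 0.45) and Pdgfb by -0.29 (SE 0.18). Without 18-month replicate 3 or 2-month replicate 3 Fgf2 gave -0.10 or -0.07. Over the alternatives Fgf13 ranged from -1.29 to -0.39 and Pdgfb from -0.42 to -0.003. Vegfa differed by -0.11 (SE 0.29), but its 2 probe sets had opposite signs. Wnt genes gave a median of 0.05 (17 tested, adjusted p = 0.913). Wnt2b was at 0.79 (SE 0.25), Rspo3 at -0.55 (SE 0.33), Sfrp5 at -0.35 (SE 0.25) and Sfrp1 at 0.20 (SE 0.17). Matrix proteases and their inhibitors fell short of the threshold (15 tested, 12 above 0, median 0.13, camera adjusted p = 0.0591; adjusted p = 0.239 with an estimated correlation). Ctss, the cathepsin S gene, was at 1.07 (SE 0.34) and Mmp14 at 0.63 (SE 0.27). Serpina3n was at 1.72 (SE 0.59, from 0.77 to 2.19 over the alternatives) and Timp4 at 2.54 (SE 0.92, from 1.32 to 3.34). Fry called this list in the upward direction (adjusted p = 0.0159), and camera did with no filter (0.0169), quantile normalization (0.0355), trend and robust estimation (0.0137) or without 18-month replicate 1 (0.0403). The chemokine genes Cxcl10 and Ccl11 and the senescence gene Cdkn2a lay below the filter at both ages.

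**Figure D4:**
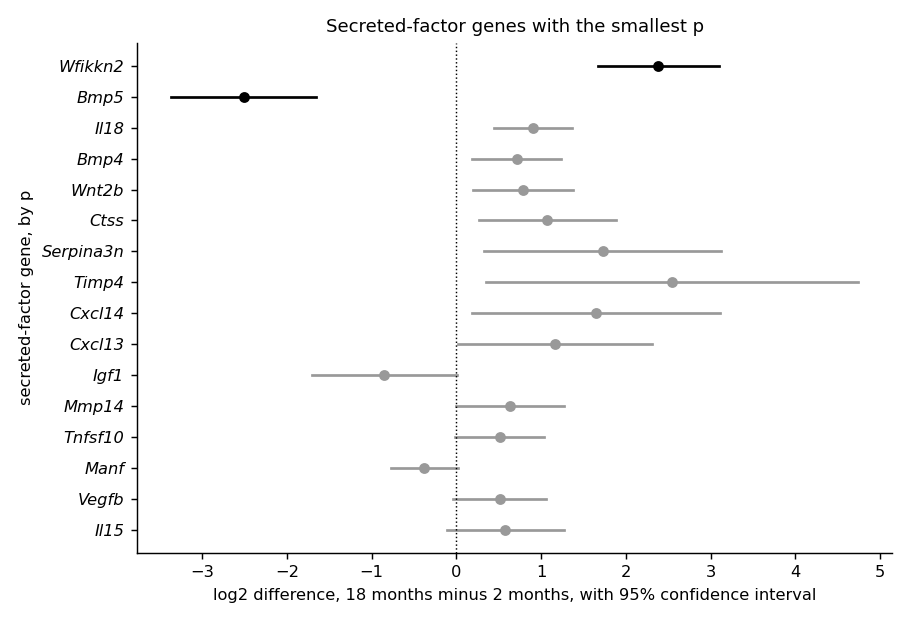
Log2 difference between ages (x axis, 18 months minus 2 months) of the secreted-factor genes with the smallest p (y axis), as a point with its 95% confidence interval from limma. Black marks genes past an adjusted p of 0.05 over the list alone, Wfikkn2 (2.38) and Bmp5 (-2.51), and grey the others.

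The epithelium's own genes went in both directions. Choroid plexus epithelium markers had a median of -0.05 (28 tested, camera adjusted p = 0.930), Wfikkn2 among them. Ranges were separate for 5 genes that were higher and 6 that were lower, and fry called the list when both directions counted (adjusted p = 0.00236). The water channel gene Aqp1 was at 0.64 (SE 0.24), Col8a1 at -0.39 (SE 0.16) and Steap1 at 0.45 (SE 0.19). Genes of ion and water transport had a median of -0.02 (21 tested, adjusted p = 0.893). The kinase gene Wnk1 was at 0.35 (SE 0.17), the potassium channel subunit gene Kcne2 at -0.31 (SE 0.16) and Car14 at 0.42 (SE 0.22). The junction list did not pass camera (23 tested, median 0.02, adjusted p = 0.857), and fry called it in either direction (adjusted p = 0.00236). Adjusted over that list alone, the polarity gene Pard3 rose (1.55, SE 0.23) and the tight junction gene Marveld3 fell (-1.22, SE 0.29). Over all genes their limma adjusted p was 0.198 and 0.494. Their smallest differences over the alternatives were 0.55 and -0.50. Cldn3 was at 0.63 (SE 0.19) and Marveld2 at 0.42 (SE 0.28). Genes of barrier transport and amyloid handling had a median of 0.07 (27 tested, adjusted p = 0.565). The peptide transporter gene Slc15a2 was at 0.95 (SE 0.27), Apoe at 0.45 (SE 0.18), Abca8a at 0.50 (SE 0.28) and Slc23a2 at -0.28 (SE 0.18). In retinoid and thyroid hormone handling (18 tested, median 0.11, adjusted p = 0.693) the retinol dehydrogenase gene Rdh10 rose when adjusted over the list alone (0.95, SE 0.20). Iron and copper genes (20 tested, median -0.01, adjusted p = 0.748) included the ferroxidase gene Heph (-1.65, SE 0.51) and Mt3 (-1.10, SE 0.40).

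Vascular and stromal cell markers gave no shift past the threshold. Medians were 0.18 for endothelium (18 tested, adjusted p = 0.713) and -0.16 for pericytes and smooth muscle (11 tested, 0.525). Over the alternatives the first ranged from 0.01 to 0.28 and the second from -0.28 to 0.01. For fibroblasts and meningeal stroma the median was -0.20 (19 tested, 0.586), and for collagens and basement membrane -0.07 (32 tested, 0.903). Within these, Ramp2 differed by 1.08 (SE 0.35) and Myl9 by -0.47 (SE 0.19). Of the stromal markers Pdgfra rose when adjusted over the list alone (adjusted p = 0.00137), against Ogn at -0.80 (SE 0.27) and Dcn at -0.72 (SE 0.25), and the collagen gene Col18a1 differed by 0.85 (SE 0.23). Stromal markers passed in the downward direction without 18-month replicate 3 (median -0.38, adjusted p = 0.0268) and without both arrays at the ends of component 1 (-0.57, 0.00432). Without 18-month replicate 2 or 2-month replicate 3 their median was 0.05 or 0.03. Neuron markers had a median of 0.15 (18 tested, adjusted p = 0.857), astrocyte and stem cell markers 0.16 (14 tested, 0.713) and erythrocyte markers -0.08 (6 tested, 0.865). Neuron markers passed upward without 18-month replicate 1 (median 0.44, adjusted p = 0.0278) or 2-month replicate 3 (0.43, 0.0298), and downward without both arrays at the ends of component 1 (-0.49, 0.00432). Cell cycle genes had a median of -0.20 (19 tested, 13 below 0, adjusted p = 0.131), and passed downward without 2-month replicate 2 (adjusted p = 0.0159). The replication helicase gene Mcm6 differed by -3.06 (SE 0.81), but its 18-month mean lay at background, which its 2-month mean exceeded by 2.65, and the proliferation marker Mki67 differed by -0.69 (SE 0.60). The p53 and senescence list (17 tested, median 0.04, adjusted p = 0.865), oxidative phosphorylation (48 tested, 0.03, 0.865) and ribosomal proteins (25 tested, 0.00, 0.888) did not pass. Neither did antioxidant enzymes (29 tested, -0.06, 0.888) or the heat shock response (17 tested, -0.07, 0.310). In these lists Zmat3 was at 0.75 (SE 0.30), Ndufb3 at 0.40 (SE 0.19), Rps6 at 0.34 (SE 0.24), Gpx3 at 0.93 (SE 0.23) and Hspa4l at -0.53 (SE 0.25). The mean had the opposite sign to the median for choroid plexus epithelium (0.08), ion transport (0.04), collagens (0.02), antioxidant enzymes (0.01), BMP ligands (0.01), insulin-like growth factors (-0.03) and lymphocyte markers (0.14). Camera gave the direction of the mean for ion transport and insulin-like growth factors and of the median for the others.

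When all 45037 probe sets were tested without naming genes, 1 passed an adjusted p of 0.05 and 2558 had an unadjusted p under 0.05. Probe set 1458719_at, which has no gene name in the annotation, had a log2 intensity of 2.78 ± 0.27 at 18 months against 7.50 ± 0.34 at 2 months (SD, n = 3 each), a difference of -4.72 (SE 0.24, adjusted p = 0.0270). The 18-month values are not above background, so no fold is given, only a bound. The 2-month mean lay 3.00 (log2) above the highest bacterial control. The probe set was named after its value was seen. Leaving out any one mouse ended this call, with 0 probe sets passing in each of the 6 fits.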

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

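One result came from data outside the comparison of genes. Among the probe sets without a gene name, 1458719_at gave a difference of -4.72 on the log2 scale. All 3 mice at 18 months were at the level of the bacterial control probe sets, so that only a bound holds, a 2-month mean 3.00 above the highest of those controls. What it detects was not analysed here.

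All 10 splits of the 6 arrays into 3 and 3 were refitted, a test chosen after the results were seen. The split by age gave 0 genes at an adjusted p under 0.05, as did all 10 splits. It gave 894 genes at an unadjusted p under 0.05 against a highest of 763 in another split, 12 gene lists by camera against a highest of 7, 2 secreted-factor genes against 0 and 1 probe set against 0, so that in each of these 1 split of 10, the real one, reached its own value. With 10 splits no share can be under 0.1, which is too few for a test at 0.05.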

How the results depend on the processing

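The settings here were fixed before the data were examined, except the neuron covariate, the fit without the arrays at both ends of component 1, and leaving mice out of the array similarity and control probe values. Genes higher numbered 3 with a 60th percentile filter, 5 with the mean of all probe sets, 3 with array weights, 2 with trend and robust estimation, 1 with the neuron covariate and 5 at an adjusted p under 0.10, and genes lower 1 with the 60th percentile filter, 1 with array weights and 1 at 0.10. Both were 0 in every other fit, including all 6 without a mouse. Lists higher numbered 5 with the 60th percentile filter, 6 with the mean of all probe sets, 4 without the arrays at both ends of component 1, 0 with an estimated correlation and 1 by fry, and 6 to 11 without a mouse. Lists lower numbered 0 with an estimated correlation, 0 by fry, and 1 to 3 without a mouse. Secreted-factor genes were 0 over all genes in every fit. Over the list alone they numbered 3 with no filter (Ccl8 added), 3 with the 60th percentile filter (Il18 added), 3 with the neuron covariate (Serpina3n added), 3 at an adjusted p under 0.10, 1 with the mean of all probe sets, 0 without the arrays at both ends of component 1, 0 by the ordinary 2-sample test and 0 to 2 without a mouse. Probe sets numbered 0 without any one mouse. The cause was not tested for these shifts, except that a stricter filter and fewer mice leave fewer genes or samples by construction. The variance between ages was 27.1% to 30.1% without a mouse, where fewer arrays raise the share expected by chance. The age difference in the Gapdh control value lay between -0.22 and -0.07 without a mouse. The median of oligodendrocyte markers turned to -0.50 without the arrays at both ends of component 1, which differ in brain signal.

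Nothing in the labels pairs the mice by replicate number. Deviations of same-numbered arrays correlated at -0.02, 0.02 and 0.17. The 18-month replicates 2 and 3 correlated best with the 2-month array of their own number and replicate 1 with 2-month replicate 2. With the replicate number as a block, 0 genes were higher, 0 lower, 10 lists higher and 2 lower, with cholesterol genes lost (0.0564) and matrix proteases gained (0.0496). In that fit 0 secreted-factor genes passed over the list alone and 0 probe sets passed.

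Lists for MHC class II, macrophages, the clock and immediate-early genes passed without each mouse in turn, though immediate-early genes did not pass without the arrays at both ends of component 1 (adjusted p = 0.0571). That fit also ended the calls for chemokines (0.276), cholesterol (0.0571), glucocorticoid genes (0.117), glycolysis (0.0571), oligodendrocytes (0.146) and chaperones (0.0933), and it leaves only 4 arrays. The 60th percentile filter ended those for MHC class I, chemokines, glucocorticoid genes, glycolysis and oligodendrocytes, and the mean of all probe sets those for MHC class I, cholesterol, glucocorticoid genes and glycolysis. Of 173 named genes, 7 passed 0.05 under some setting, and 63 gave a difference over 1.5 times smaller, or of the other sign, without some mouse. Of those 63, 5 had an unadjusted p under 0.05. The neuron covariate ended the call for glucocorticoid genes, and leaving out shared genes that for glycolysis.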

Other observations

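All tests in this part were chosen after the results were seen, on the same data. Some pituitary hormone transcripts other than Gh were also higher at 18 months. Prl, prolactin, went from 3.00 ± 0.09 to 6.29 ± 1.18, Cga, the shared subunit of glycoprotein hormones, from 3.18 ± 0.18 to 5.44 ± 0.96, and Pomc from 6.38 ± 0.28 to 7.72 ± 0.83 (log2 intensity, SD, n = 3 each). The others did not separate the ages. Tshb differed by 0.44 (SE 0.36), Lhb by -0.04 (SE 0.27) and Fshb by 0.03 (SE 0.24). The means of Tshb and Fshb lay under the highest bacterial control (4.51) at both ages. Of the 3 mice at 18 months, replicate 3 was lowest for Gh, Prl, Cga and Pomc.

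For Gh, cross-hybridisation of 1 probe set is argued against by its 4 probe sets, all higher by at least 3.64 over their 2-month mean or background. Pituitary RNA in the 18-month samples is a candidate explanation, since it needs Prl to be higher too, and Prl differed by 3.30 (SE 0.55). Prl lay at background at 2 months and below the filter, so only a bound holds, an 18-month mean 1.79 above the highest bacterial control. Its values at 18 months were 6.42, 7.40 and 5.06. The 18-month mean of Cga lay only 0.94 above that control, and replicate 3, at 4.40, lay under it. Lhb gives this explanation no support, while Tshb and Fshb, with means under that control at both ages, cannot tell. Expression of these hormone genes in the aged plexus itself stays open and was not tested.

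For the MHC class II genes, the first explanation is more macrophages of every kind at the same class II level per cell. The values here cannot settle it. The median of 21 macrophage markers was 0.40 (SD 0.77 between genes, and no higher than 0.52 in any fit). The smallest difference among H2-Aa, H2-Ab1 and Cd74 was 2.41. But these 3 genes had the smallest p of their list, whose own median was 1.04, so that their selection alone favours a gap. Single macrophage markers came closer to 2.41, such as Ms4a7 (2.04, SE 0.35), while 4 of the 21 were below 0. A median over the list cannot tell whether a subset of cells rich in class II grew in number. CD1 mice are outbred, and variants in the H2 genes could change probe binding, though not for Cd74, which lies outside the H2 region (2.41, SE 0.41) and whose own variants were not tested. A variant under 1 probe set of H2-Ab1 is argued against by its 3 probe sets, all higher by at least 1.95 over their 2-month mean or background, while a variant in sequence they share was not tested. For H2-Aa a variant cannot be told apart from a change in level, since its probe sets above the filter gave as little as 0.73. More macrophages of every kind, more cells rich in class II and a higher class II level per cell with age all stay open.

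For the clock genes, collection at another phase of the day in the 18-month group cannot be told apart from other causes. The test asked whether the genes set as opposite in phase, Arntl, Clock, Npas2 and Nfil3, were lower. Their mean differed by -0.34, but the ages overlapped for all 4 genes and Clock went the other way (0.25, SE 0.29). Of the genes in the Per and Dbp phase, Nr1d1 differed by 0.04 (SE 0.18), and it, Per1, Ciart and Bhlhe41 overlapped between ages. Per2, Per3, Nr1d2, Dbp, Tef, Hlf and Bhlhe40 lay in separate ranges. Acute stress before collection cannot be told apart either, since glucocorticoid-induced genes had a median of 0.21 but lost their call without any of 3 of the mice. A clock shifted by age itself was not tested, and the labels give no time of collection.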
